A study of Arabidopsis thaliana with 2 samples.

How the data were processed

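The series holds RNA sequencing of whole Arabidopsis thaliana seedlings of accession Columbia at day 10 after germination, with a control group and a group given 1 µmol/L flg22 for 4 h. Per the labels, total RNA was extracted with a commercial plant RNA kit from frozen samples, libraries were made and sequenced on an Illumina HiSeq instrument, and 3 biological replicates were pooled in each library. Groups were taken from the treatment label, giving 1 control and 1 flg22 library. No statement on strand was found in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

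The authors deposited a table of 27416 genes with read counts and RPKM for each library, per the file headers. The submitters' processing notes name Bowtie, TopHat, DESeq and the TAIR10 genome, without versions or roles; the counting program and its rule for overlapping genes are not given in the sources used here. The deposited read counts were whole numbers and were used as raw counts. RPKM as deposited by the authors equalled reads divided by the listed gene length and by the column's total, to within 7.24e-06% for every gene with reads. The length, headed as exon length per the file headers, lay closer to the whole gene span than to the exons. Among 16096 genes whose span in the reference exceeds their joined exons by over 20%, the median deposited length was 0.959 of the span and 1.42 times the exons. RPKM of genes with long introns is therefore low, while the ratio between libraries is touched only through the added constant. The authors' comparison gives a log2 fold change, a p-value and an FDR per gene, per the file headers; its log2 fold changes are shifted by 0.04 against ratios scaled by column totals. It lists no value for the 4002 genes without reads in either library and an infinite log2 fold change for 1399 genes with reads in only 1 library. With 1 library per group, p-values of that table cannot reflect spread between replicates. A further 2 columns of scaled counts per library were not used.

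From the deposited RPKM, log2((flg22 + 1)/(control + 1)) was computed for each gene, and genes with a mean of at least 1 RPKM over both libraries were kept, 18724 in all. Genes past 2-fold on that scale were counted in each direction by size alone, since no test is possible without replicates. For 24 lists holding 460 genes, of which 459 were analysed here, the median log2 ratio of the members past the filter was placed among the medians of 10000 random lists of the same size, matched on mean log2(RPKM + 1) in 20 bins. A list was called apart in the outer 2.5% on either side, as a description of these libraries and not as a p-value. The lists covered aliphatic and indolic glucosinolate biosynthesis, glucosinolate breakdown and transport, tryptophan, camalexin and sulfur metabolism, flg22 markers, early signalling, WRKY factors, salicylic acid, jasmonate, ethylene, abscisic acid and cold, auxin, phenylpropanoids, flavonoids, photosynthesis, endoplasmic reticulum folding, heat shock, cell division, cell expansion, the clock, root markers and reference genes. No gene was placed in more than 1 list.

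For a ratio in folds, reads were divided by the column total, and the interval is the exact conditional binomial (Clopper-Pearson) interval at 95%. Reads carry no molecular identifiers, so intervals and floors cover counting error only and not the difference between plants or preparations. A count of 0 was replaced by a floor of 3 reads per library for a lower bound, which equals 0.140 CPM (reads scaled to the library total) in the control library and 0.122 CPM in the flg22 library. Genes with 1 to 3 reads keep their ratio and interval.

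Lists, thresholds and the rule for named genes were set before the data were examined. The rule took the 10 highest and the 10 lowest log2 ratios among nuclear genes reaching 5 RPKM and 50 reads in the higher library. It added up to 6 genes past 2-fold in each direction of the glucosinolate biosynthesis lists, the 3 largest differences of every other list, and FRK1 and FLS2, for 90 genes in all. Any other gene is said to lie outside the rule or to have been picked after its value was seen. Gene symbols come from the lists or from the RefSeq annotation of assembly TAIR10.1, in which 26719 of the 27416 identifiers were found; because the authors' build differs from it in name, no coordinates are given and it served only for names, lengths and overlaps.

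The steps were tested on simulated data with 18701 genes past the filter, drawn as Poisson counts from the mean rates of the 2 libraries. Of genes set apart by 3 on the log2 scale and still past the filter, 100% were recovered by the 2-fold rule, 50 higher and 44 lower. Of those set apart by 1.5 and past the filter, 48 of 50 (96%) were recovered in the higher direction. In the lower direction it was 38 of 47 (80.9%). Genes that fell under the filter once set lower are not in these shares, so recovery in that direction is overstated. Among unchanged genes, 9 of 18510 passed 2-fold by counting noise. Of 200 unchanged simulated lists of 20 genes, 9 (4.5%) were called apart, and of 50 lists shifted by 1 on the log2 scale, all 50 were. The simulation holds no difference between plants and no shared regulation of list members. These rates therefore describe counting noise, not how often lists of related genes are called apart.

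Alternatives set beforehand were an added constant of 0.1 or 5 RPKM, no filter or a mean of at least 5 RPKM, centring on the median of all genes, on a trimmed mean or on the reference genes, CPM in place of RPKM, a 4-fold limit, a counting interval that excludes 1, and unmatched random lists. Scaling by the authors' log2 shift, keeping 1 gene per cluster of neighbouring list members, other groupings of the clock genes, counts of list members with no added constant and the starvation list without the filter were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.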

Results

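Messenger RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana, accession Columbia, at day 10 after germination. Seedlings were either left as controls or treated with flg22, a peptide from the conserved part of bacterial flagellin that plants perceive through the receptor kinase FLS2, at 1 µmol/L for 4 h. Each group was 1 library, made from a pool of 3 biological replicates, so the data hold 2 libraries. Gene counts summed to 21414567 reads in the control library and 24621440 in the flg22 library, over 27416 listed genes. At least 1 read was counted for 22538 genes in the control library and for 22891 in the flg22 library. Chloroplast and mitochondrial genes together took 0.0178% of the control reads and 0.0185% of the flg22 reads. The 10 most abundant genes took 4.51% of the control reads and 2.58% of the flg22 reads. Because the replicates were pooled before sequencing, no difference given here has a replicate check, and no p-value of the present calculations is given. Values are RPKM as deposited, which are read counts scaled for gene length and library total. The log2 ratios are of flg22 over control after adding 1 RPKM, which understates the ratio of weakly expressed genes. Counts of genes past or within a fold limit are on this log2 scale; with no added constant, 10 more list members would be at least 2-fold higher and 8 more lower. Ratios in folds are of reads per library total with no added constant, and the range in parentheses after each is its exact 95% counting interval, which covers counting error in these libraries only.

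The first comparison asked which genes differed between treated and control seedlings. FRK1, a receptor-like kinase gene commonly used as a marker of the flg22 response, served as a check of the labels. FRK1 (AT2G19190) was at 1.01 RPKM in the control library and 85.7 RPKM in the flg22 library, a ratio of 85.1-fold (68.7 to 107). The receptor gene itself, FLS2 (AT5G46330), was at 22.3 and 28.2 RPKM, a ratio of 1.27-fold (1.19 to 1.34). Among the 18724 genes with a mean of at least 1 RPKM, 2111 (11.3%) were at least 2-fold higher with flg22 and 1548 (8.27%) at least 2-fold lower. Differences of 8-fold or more were found for 318 genes in the higher direction and 53 in the lower. The median log2 ratio over these genes was -0.03, with quartiles at -0.44 and 0.42. With 5 RPKM added in place of 1, the 2-fold counts were 1392 higher and 830 lower, and at a 4-fold limit they were 781 and 279. With all ratios centred on the reference genes they were 1862 higher and 1960 lower, so which direction held more genes depended on the scaling.

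**Figure D1:**
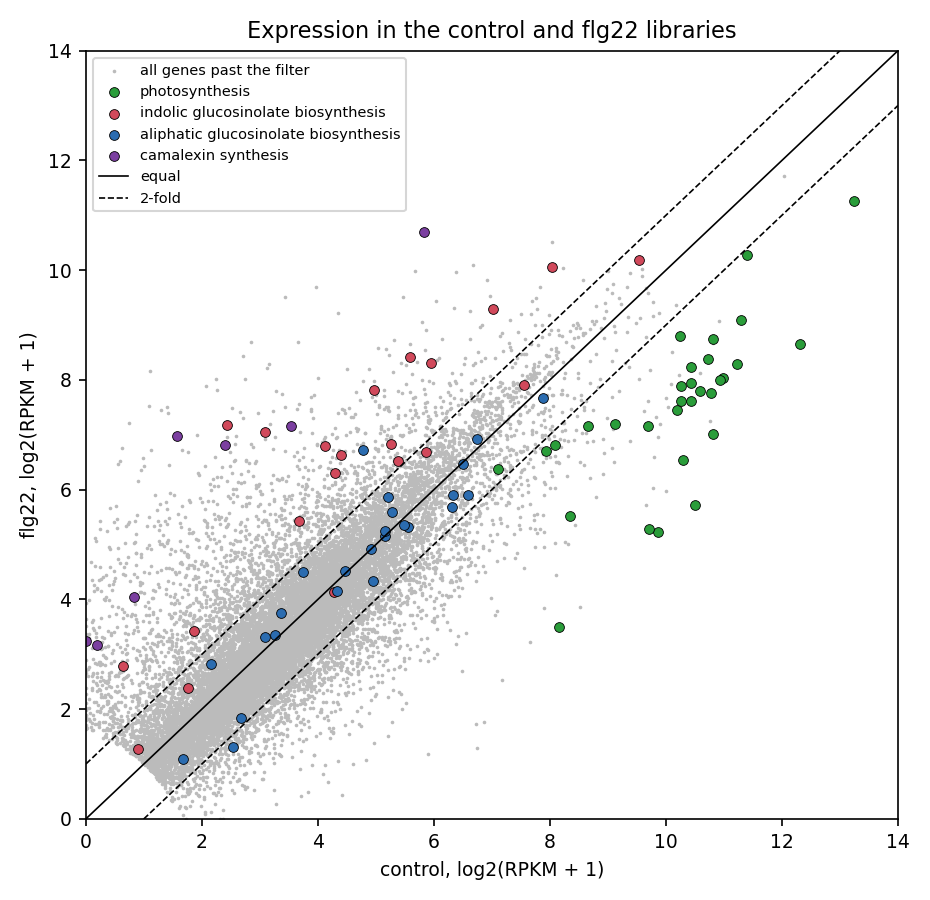
Each point is a gene with a mean of at least 1 RPKM, placed by log2(RPKM + 1) in the control library (horizontal axis) and in the flg22 library (vertical axis), with 1 library per axis. The solid line marks equal values and the dashed lines 2-fold differences; 30 of the 31 photosynthesis genes lie beneath the lower dashed line, and 15 of the 21 indolic glucosinolate genes lie above the upper one.

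The 10 highest log2 ratios among well-covered nuclear genes lay between 5.92 and 7.05. AT2G17740, which encodes a cysteine- and histidine-rich C1 domain protein, had the highest log2 ratio, 7.05, and was at 1.16 RPKM in the control library and 285 RPKM in the flg22 library. PROPEP3 (AT5G64905), the precursor of a danger peptide that amplifies immune signalling, was 219-fold higher (106 to 546). MLO12 (AT2G39200), a member of the family of powdery mildew susceptibility genes, was 119-fold higher (98.97 to 144), and the peroxidase genes PER4 (AT1G14540) and AT5G64120 by 100.2-fold (77.6 to 132) and 74.4-fold (67.01 to 82.9). The dirigent protein gene DIR5 (AT1G64160) was 178-fold higher (93.8 to 391), and ABR1 (AT5G64750), an ERF-type transcription factor gene, by 187-fold (125 to 292). The remaining members of this group were the aspartyl protease gene AT5G48430, with a log2 ratio of 6.44, the TIR domain gene AT1G57630, at 6.13, and AT5G36925, of unknown function, at 6.12.

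At the other end, the lowest log2 ratio was that of BXL1 (AT5G49360), a cell wall beta-xylosidase gene, which was at 106 RPKM in the control library and 1.45 RPKM in the flg22 library and so 72.96-fold lower (62.8 to 85.2). The fructose-bisphosphate aldolase gene FBA5 (AT4G26530) was 48.4-fold lower (39.9 to 59.2), the lipid-transfer-like gene AT1G62510 by 45.3-fold (33.9 to 61.9) and NCED4 (AT4G19170), a carotenoid cleavage dioxygenase gene, by 46.1-fold (36.02 to 59.9). SEN1 (AT4G35770), known to be induced in darkness and senescence, was 27.1-fold lower (24.6 to 29.97). The DUF506 gene AT2G20670 and the nucleotide hydrolase-like gene AT3G62550 were 30.2-fold lower (26.2 to 34.95) and 24.2-fold (21.3 to 27.6). The other members of this group were the light-harvesting genes LHCB1.4, LHCB2.3 and LHCB2.1, described with photosynthesis.

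In the authors' deposited table, which compared the same 2 libraries and so describes those libraries rather than the conditions, 208 genes had a false discovery rate (FDR) below 0.05, 190 of them higher and 18 lower with flg22. The smallest log2 fold change among them in the authors' deposited table was 4.15 in size. FRK1 had an FDR of 0.00100 in the authors' deposited table and FLS2 an FDR of 1.

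The second comparison concerned glucosinolates, the sulfur-rich defence compounds of the cabbage family that the study's title names. Arabidopsis makes an aliphatic class from methionine and an indolic class from tryptophan, and the genes of both classes were set side by side. Of the 21 indolic biosynthesis genes measured, 15 were at least 2-fold higher with flg22, 6 lay within 2-fold and none was at least 2-fold lower. Their median log2 ratio was 2.005, at percentile 100 of random lists matched on expression. Of the 25 aliphatic biosynthesis genes measured, 23 lay within 2-fold, 1 was higher and 1 was lower. Their median log2 ratio was -0.02, at percentile 31.0, and its sign changed with the scaling. The medians differed by 2.02, and the difference lay at percentile 100 among random pairs of lists, of which the highest was 1.87. GGP1, SUR1 (AT2G20610) and UGT74B1 (AT1G24100), of core steps that serve both classes, were counted in the indolic list alone. Their log2 ratios were 2.36, 1.14 and 1.57, so the contrast is not between class-specific genes only. SUR1 and UGT74B1 lie outside the naming rule.

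In the indolic list, IGMT2 (AT1G21120), an indole glucosinolate methyltransferase gene, had the highest ratio and was at 4.41 RPKM in the control library and 144 RPKM with flg22, 32.7-fold higher (27.7 to 38.8). CYP81F2 (AT5G57220), whose product hydroxylates the indole ring for the 4-methoxy compound, was 17.5-fold higher (15.7 to 19.6). CYP79B2 (AT4G39950), which converts tryptophan to indole-3-acetaldoxime, was 7.41-fold higher (7.02 to 7.82). SOT16 (AT1G74100), a desulfoglucosinolate sulfotransferase gene, was 7.29-fold higher (6.89 to 7.72), and GGP1 (AT4G30530), which processes glutathione conjugates in the core pathway, by 5.21-fold (4.996 to 5.44). Of the regulators, MYB51 (AT1G18570) was 6.74-fold higher (6.21 to 7.32), and MYB122 (AT1G74080), outside the naming rule and weakly expressed at 0.5599 RPKM in the control library, by 10.6-fold (6.85 to 17.2). MYB34 (AT5G60890), another activator of the indolic branch that was picked out after its value was seen, had a log2 ratio of -0.15, the only member below 0. The other members within 2-fold, outside the naming rule, were late modification and glutathione transferase genes, with log2 ratios of 0.36 for IGMT4, 0.37 for CYP81F1, 0.63 for CYP81F4, 0.65 for GSTF9 and 0.84 for IGMT5. IGMT1 to IGMT4 form a cluster of closely similar neighbouring genes, so the division of reads among them is uncertain.

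In the aliphatic list, SOT17 (AT1G18590), a sulfotransferase gene of the methionine-derived branch, was the gene past 2-fold on the log2 scale in the higher direction, by 3.97-fold (3.67 to 4.3001). AOP1 (AT4G03070), which encodes a 2-oxoglutarate-dependent dioxygenase, was the gene past it in the lower direction, by 3.27-fold (2.32 to 4.69), from 131 reads in the control library and 46 with flg22. With no added constant the regulator gene MYB29 (AT5G07690), outside the naming rule, was also lower by 2.096-fold (1.66 to 2.66), against a log2 ratio of -0.84. AOP3 (AT4G03050) was listed at 0 reads in both libraries and MYB76 (AT5G07700) had a mean under 1 RPKM; both were picked out for that reason after their values were seen. AOP2 was not analysed here.

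**Figure D2:**
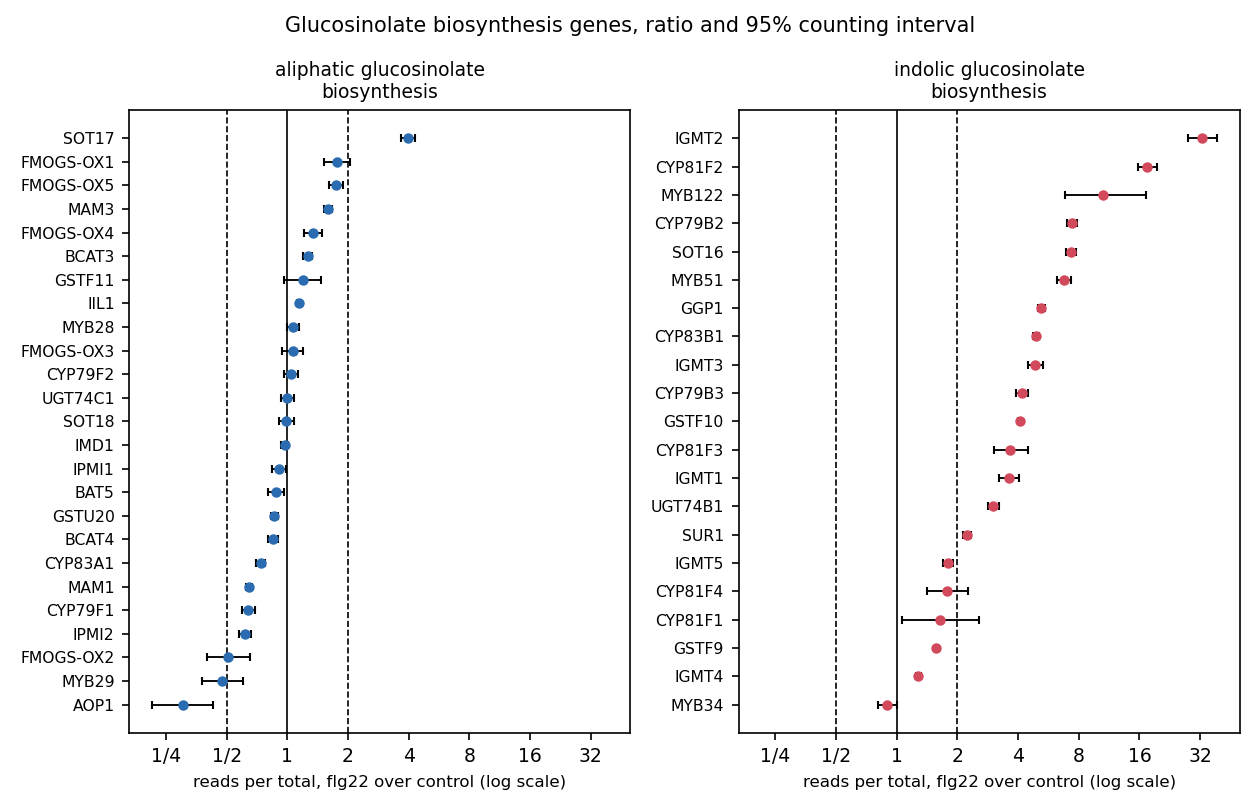
Ratio of reads per library total, flg22 over control, on a log scale for each measured gene of aliphatic (left, 25 genes) and indolic (right, 21 genes) glucosinolate biosynthesis, 1 library per group. Points are ratios, bars their 95% counting intervals, and dashed lines mark 2-fold; of the aliphatic genes SOT17 lies above the dashed lines and AOP1 and MYB29 beneath, and indolic genes range from MYB34 at 0.898 to IGMT2 at 32.7.

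Genes of glucosinolate breakdown and transport were mostly within 2-fold. Of 19 measured, 4 were higher and none lower, and the median log2 ratio was 0.16, at percentile 63.5, with a range of 0.04 to 0.27 over its settings. The genes past 2-fold included PEN2 (AT2G44490), an atypical myrosinase that cleaves indolic glucosinolates during infection, 3.15-fold higher (3.05 to 3.24). PEN3 (AT1G59870), an ABC transporter gene needed for the same defence, was 2.204-fold higher (2.17 to 2.24), and the glucosinolate transporter gene GTR1 (AT3G47960) by 2.28-fold (2.07 to 2.52). The remaining gene was NIT3 (AT3G44320), a nitrilase gene outside the naming rule, with a log2 ratio of 1.02. With no added constant MBP1 (AT1G52040), a myrosinase-binding protein gene also outside the rule, was 2.17-fold lower (1.58 to 3.01).

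Lists of pathways that feed or share the indolic branch also had medians above 0. For tryptophan synthesis, 7 of 10 genes were at least 2-fold higher and none lower, with a median log2 ratio of 2.53 at percentile 100. The tryptophan synthase gene TSA1 (AT3G54640) was 10.95-fold higher (10.5 to 11.5), the anthranilate synthase gene ASB1 (AT1G25220) by 8.96-fold (8.27 to 9.71) and the indole-3-glycerol phosphate synthase gene IGPS (AT2G04400) by 8.64-fold (8.12 to 9.21). The camalexin list, named for the indole phytoalexin of Arabidopsis, also held FOX1 and CYP82C2 of a related indole cyanogenic pathway and the transporter gene ABCG40, outside the naming rule. All 7 of its genes were at least 2-fold higher, with a median log2 ratio of 3.63 at percentile 100. The oxidase gene FOX1 (AT1G26380) was 63.1-fold higher (50.4 to 80.3), the glutathione transferase gene GSTF6 (AT1G02930) by 29.96-fold (28.5 to 31.5) and CYP71A12 (AT2G30750) by 25.8-fold (22.4 to 29.998). GSTF6 and CYP71A12 each have a close neighbouring copy with which reads can be shared. CYP82C2 (AT4G31970), singled out because it had 0 reads in the control library and 405 with flg22, was at least 117-fold higher against a floor of 3 reads in the control library, and the lower limit of its exact counting interval was 95.1-fold. With CYP82C2 placed at the bound from the floor, which has no added constant, the camalexin median was 4.40. The other members kept their added constant, so this median is not on the same scale as 3.63.

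In sulfur assimilation, which supplies reduced sulfur and the sulfate donor for glucosinolates, 11 of 22 genes were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.98 at percentile 100. APK2 (AT4G39940), which makes the activated sulfate used in the last core step, was 8.27-fold higher (7.79 to 8.79), the serine acetyltransferase gene SERAT2;1 (AT1G55920) by 3.31-fold (3.09 to 3.54) and the sulfur-deficiency-inducible gene LSU1 (AT3G49580) by 3.44-fold (2.64 to 4.54). The gene that was lower was the sulfate transporter gene SULTR2;1 (AT5G10180), outside the naming rule, with a log2 ratio of -1.30.

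The third comparison covered immune signalling and defence hormones. All 10 flg22 marker genes were at least 2-fold higher, with a median log2 ratio of 4.31 at percentile 100 (2.87 with 5 RPKM added); AT2G17740, PROPEP3 and PER4, given with the highest ratios, led them. Of 31 genes for pattern recognition and early signalling, 23 were at least 2-fold higher and none lower, with a median log2 ratio of 1.38 at percentile 100. The ubiquitin ligase genes PUB23 (AT2G35930) and PUB22 (AT3G52450), negative regulators of this signalling, were 31.9-fold higher (27.5 to 37.1) and 22.7-fold (19.5 to 26.6), and the receptor-like kinase gene IOS1 (AT1G51800) by 24.6-fold (22.6 to 26.8). Whole families, grouped after the values were seen, were mixed. The median was 0.11 over 19 measured PUB genes, at percentile 78.4, and 0.09 over 16 MPK genes, at percentile 66.0. Over 19 CPK genes it was 0.79, at percentile 99.98. Among 31 WRKY transcription factor genes, 26 were at least 2-fold higher and none lower, and the median log2 ratio was 2.35, at percentile 100. Over all 51 measured genes with a WRKY symbol, grouped after the values were seen, the median was 1.22, at percentile 100. Of these 51 genes, 31 were at least 2-fold higher. As 30 of the 51 already belonged to a list set beforehand, this median largely repeats the list result. The WRKY genes outside the lists were not tested apart. WRKY40 (AT1G80840) was 45.95-fold higher (37.95 to 56.2), WRKY29 (AT4G23550) by 22.03-fold (18.4 to 26.54) and WRKY46 (AT2G46400) by 29.4-fold (20.2 to 44.5).

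For salicylic acid, 7 of 15 measured genes were at least 2-fold higher and none lower, with a median log2 ratio of 0.92 at percentile 99.99 (0.61 with 5 RPKM added). The transcriptional regulators CBP60G (AT5G26920) and SARD1 (AT1G73805) were 27.3-fold higher (21.6 to 34.8) and 18.7-fold (11.98 to 30.995), and the salicylic acid exporter gene EDS5 (AT4G39030) by 5.48-fold (4.72 to 6.397). PR1 (AT2G14610), a late marker of this hormone looked up after the values were seen, had 0 reads in the control library and 2 with flg22, so no difference was detectable at this depth. For jasmonate, 12 of 26 genes were higher and none lower, with a median log2 ratio of 0.94 at percentile 100, and 7 members had ratios below 0. CYP94B3 (AT3G48520), which inactivates the active hormone, was 49.2-fold higher (30.96 to 83.3), the lipoxygenase gene LOX4 (AT1G72520) by 40.4-fold (31.2 to 53.2) and the repressor gene JAZ1 (AT1G19180) by 14.9-fold (13.6 to 16.4). For ethylene, 10 of 19 genes were higher and none lower, with a median log2 ratio of 1.204 at percentile 100 (0.74 with 5 RPKM added). Genes of its rate-limiting enzyme led the list, with ACS7 (AT4G26200) higher by 33.7-fold (23.8 to 49.1), ACS2 (AT1G01480) by 15.2-fold (11.2 to 20.9) and ACS6 (AT4G11280) by 8.94-fold (7.94 to 10.1). A further gene of that enzyme, ACS8 (AT4G37770), outside the naming rule, had a log2 ratio of 0.16.

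Genes of phenylpropanoid, lignin and callose synthesis were higher in 14 of 19 cases and lower in none, with a median log2 ratio of 1.47 at percentile 100. The callose synthase gene of the list, PMR4 (AT4G03550), outside the naming rule, lay within 2-fold at a log2 ratio of 0.40. CCR2 (AT1G80820), a cinnamoyl-CoA reductase gene, was 17.7-fold higher (14.9 to 21.2), and the phenylalanine ammonia-lyase genes PAL1 (AT2G37040) and PAL2 (AT3G53260) by 8.398-fold (8.12 to 8.69) and 6.25-fold (6.02 to 6.498). Of the flavonoid and anthocyanin list only 9 of 18 genes were measured at a mean of 1 RPKM or more; 5 of these were higher and none lower, with a median log2 ratio of 1.07 at percentile 99.88. Without the expression filter that median was 0.40, and it was 0.70 with 5 RPKM added. The genes under the filter included DFR, LDOX, 5MAT, TT19, PAP1 and PAP2 of the anthocyanin branch, outside the naming rule. Below 0 among the measured genes were UGT75C1 (AT4G14090), at a log2 ratio of -0.14, and F3'H (AT5G07990), at -0.01, also outside the rule. MYB4 (AT4G38620), a repressor of the phenylpropanoid pathway, was 3.26-fold higher (2.91 to 3.65), the activator gene MYB111 (AT5G49330) by 4.42-fold (3.08 to 6.51) and the chalcone isomerase gene CHI (AT3G55120) by 2.64-fold (2.21 to 3.16). F3H (AT3G51240), singled out because it was listed at 0 reads in both libraries, has 94.5% of its span under an annotated antisense gene in the reference.

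Both chaperone lists had medians above 0. In endoplasmic reticulum folding, 7 of 15 genes were higher and none lower, with a median log2 ratio of 0.81 at percentile 99.4. The luminal chaperone genes BIP3 (AT1G09080), BIP2 (AT5G42020) and BIP1 (AT5G28540) were 71.7-fold higher (34.6 to 179), 3.91-fold (3.79 to 4.05) and 3.08-fold (2.98 to 3.17), and because these copies are alike in sequence the division of reads among them is uncertain. All 9 measured heat shock genes were at least 2-fold higher, with a median log2 ratio of 2.70 at percentile 100 (1.498 with 5 RPKM added). HSP70-4 (AT3G12580) was 18.3-fold higher (15.98 to 21.1) and HSP90.1 (AT5G52640) by 15.7-fold (13.6 to 18.24). For the small heat shock gene HSP17.6II (AT5G12020), 2 reads in the control library and 164 with flg22 gave a ratio of 71.3-fold (19.4 to 594).

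The fourth comparison covered photosynthesis, growth and the lists kept as checks. Photosynthesis had the lowest median of all 24 lists. Of its 31 genes, 30 were at least 2-fold lower with flg22 and none higher, with a median log2 ratio of -2.64 at percentile 0. These genes took 6.65% of the reads in the control library and 1.23% in the flg22 library. LHCB1.4 (AT2G34430) was at 1446 RPKM in the control library and 52.03 RPKM with flg22, 27.8-fold lower (26.3 to 29.4). LHCB2.3 (AT3G27690) and LHCB2.1 (AT2G05100) were 27.8-fold lower (24.6 to 31.5) and 25.5-fold (23.9 to 27.1). All encode light-harvesting proteins of photosystem II and belong to families of near-identical copies, so values of single copies are uncertain. The member within 2-fold, identified after the values were seen, was the Rubisco small subunit gene RBCS1B (AT5G38430), with a log2 ratio of -0.74. In the authors' deposited table, 4 photosynthesis genes had an FDR below 0.05, all lower. Beside this, the circadian clock list, kept as a check on the time of harvest, had a median log2 ratio of -0.33 at percentile 4.05, with 3 of 17 genes lower and none higher. With 5 RPKM added its median was -0.25, at percentile 1.81. Those 3 genes, all expressed in the morning or around noon, were PRR7 (AT5G02810), 2.97-fold lower (2.803 to 3.14), LNK2 (AT3G54500), by 3.06-fold (2.82 to 3.33), and CCA1 (AT2G46830), by 3.43-fold (2.65 to 4.49); with no added constant the morning gene RVE8 (AT3G09600), outside the naming rule, was also lower by 2.18-fold (1.53 to 3.15). The root marker list, kept as a check on the share of root tissue, had a median log2 ratio of -0.28 at percentile 9.97, with 1 of 14 genes higher and 1 lower; over its settings the median ranged from -0.46 to -0.11. RHD2 (AT5G51060), an NADPH oxidase gene of root hairs, was 2.55-fold higher (2.27 to 2.87), TIP2;3 (AT5G47450), a tonoplast aquaporin gene, was 3.45-fold lower (2.15 to 5.73), and CASP2 (AT3G11550), of the Casparian strip, had a log2 ratio of -0.88. With no added constant CASP2 was 2.05-fold lower (1.59 to 2.66) and the root hair expansin gene EXPA7 (AT1G12560), outside the naming rule, was 2.03-fold higher (1.59 to 2.61).

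Growth lists were lower by smaller amounts. In cell expansion, 8 of 14 genes were at least 2-fold lower and 1 higher, with a median log2 ratio of -1.07 at percentile 0.04. By whole families, grouped after the values were seen, the median was 0.23 over all 16 measured EXPA genes, at percentile 86.02, and -0.28 over 24 XTH genes, at percentile 3.4. The expansin gene EXPA8 (AT2G40610) was 14.1-fold lower (11.8 to 17.1), and the aquaporin genes TIP1;2 (AT3G26520) and TIP2;1 (AT3G16240) by 6.59-fold (6.39 to 6.79) and 6.12-fold (5.91 to 6.34); the gene that was higher was another expansin gene, EXPA10 (AT1G26770), outside the naming rule, at a log2 ratio of 1.70. All 15 cell division genes had ratios below 0, but on the log2 scale only 1 was 2-fold lower, and their median log2 ratio was -0.71 at percentile 0.05 (-0.44 with 5 RPKM added). The gene past 2-fold was the cyclin gene CYCB1;4 (AT2G26760), 2.45-fold lower (2.01 to 2.999). The next largest differences were a log2 ratio of -0.93 for the cyclin gene CYCD3;1 (AT4G34160) and -0.86 for the cytokinesis syntaxin gene KN (AT1G08560). With no added constant CDKB1;2 (AT2G38620), a cell cycle kinase gene outside the naming rule, was also lower by 2.102-fold (1.62 to 2.74). In auxin response and transport, 5 of 16 genes were lower and none higher, with a median log2 ratio of -0.52 at percentile 0.46. Over all 18 measured IAA genes, grouped after the values were seen, the median was -0.17, at percentile 16.2, with 2 higher and 3 lower. The Aux/IAA genes IAA29 (AT4G32280) and IAA3 (AT1G04240), whose family represses auxin response, were 8.31-fold lower (7.21 to 9.62) and 2.76-fold (2.48 to 3.07), and the efflux carrier gene PIN7 (AT1G23080) by 3.13-fold (2.98 to 3.29); the others, outside the naming rule, were PIN3 (AT1G70940) at a log2 ratio of -1.35 and IAA6 (AT1G52830) at -1.16.

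The abscisic acid and cold list did not move one way. Of 15 genes, 2 were higher and 2 lower, with a median log2 ratio of -0.13 at percentile 25.1. Over members with a mean of at least 5 RPKM the median had the other sign, 0.73 at percentile 95.4. The cold-regulated genes KIN1 (AT5G15960) and COR15A (AT2G42540) were 14.4-fold higher (12.2 to 17.1) and 3.84-fold (3.596 to 4.09), the former with a similar neighbouring copy. The abscisic-acid-responsive gene RD29B (AT5G52300) was 12.4-fold lower (8.16 to 19.7), and the other gene past 2-fold on the log2 scale was RAB18 (AT5G66400), outside the naming rule, at -1.53. With no added constant the cold regulators CBF3 (AT4G25480) and CBF2 (AT4G25470), also outside the rule, were 2.43-fold lower (1.4995 to 4.04) and 2.13-fold (1.58 to 2.901). The reference genes, commonly used for normalisation, had a median log2 ratio of 0.12 at percentile 44.7, and 18 of 19 lay within 2-fold. The exception was the ubiquitin-conjugating enzyme gene UBC9 (AT4G27960), 3.296-fold higher (3.12 to 3.48). Next in size were GAPC1 (AT3G04120), with a log2 ratio of 0.56, and ACT2 (AT3G18780), with -0.42. Centring all ratios on these reference genes would lower each log2 ratio by 0.12.

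**Figure D3:**
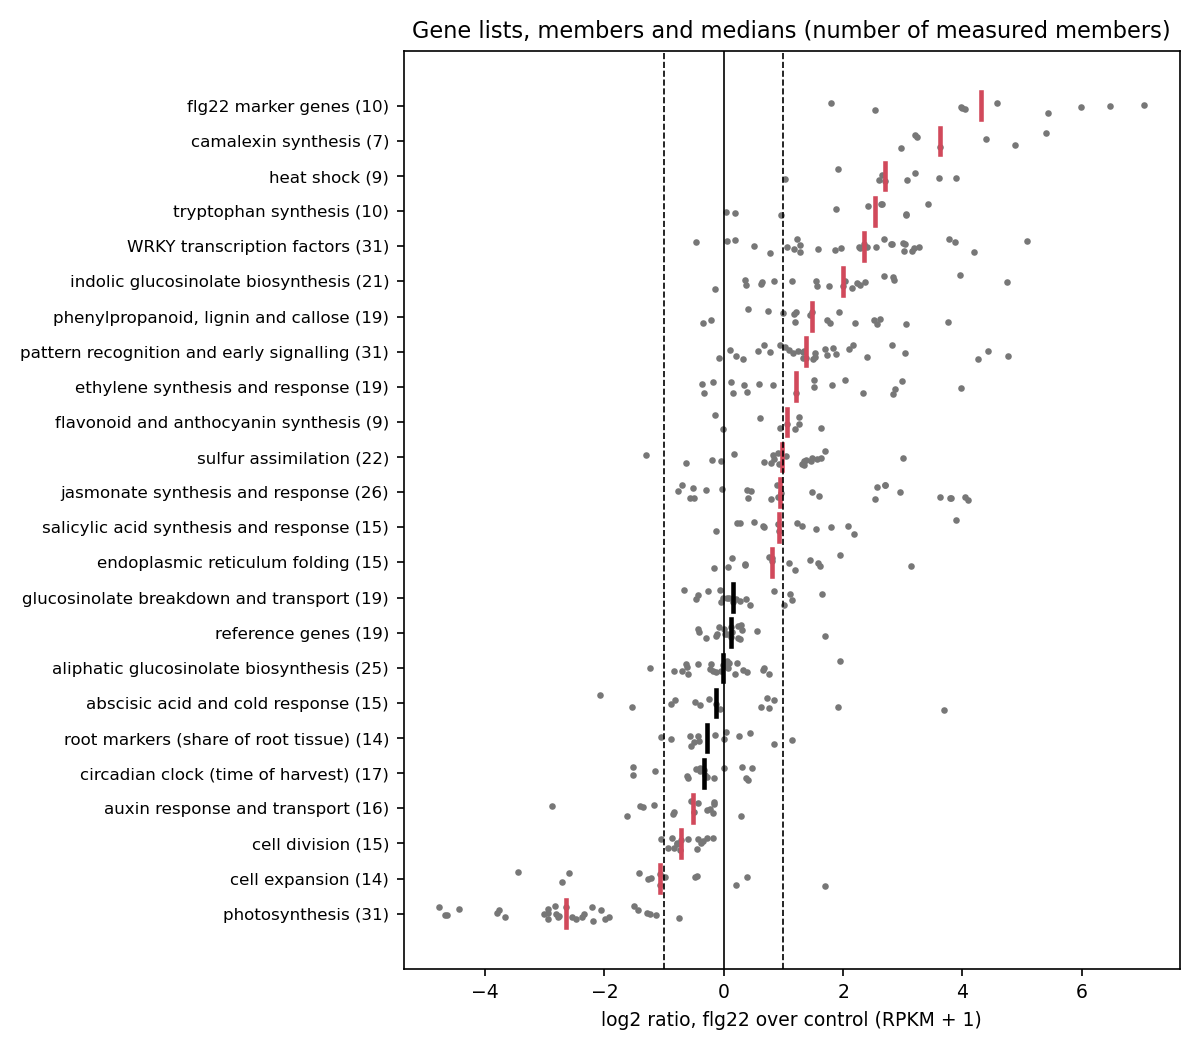
Log2 ratio of flg22 over control (RPKM + 1, horizontal axis) for each measured gene (grey points) of the 24 lists, with 1 library per group and the number of measured genes after each name. Vertical bars are medians, red where the median lay in the outer 2.5% of random lists on either side and black otherwise; medians run from -2.64 for photosynthesis to 4.31 for flg22 marker genes.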

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

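The authors' scaling, the lists with 1 gene per cluster of neighbours, the groupings of clock genes by phase, counts with no added constant and the starvation list without the filter were chosen only after the data were seen; all other settings were planned. Over 253 recalculated medians of the 24 lists, 252 stayed on their side of the 2.5% bounds with the direction of every list called apart kept. The exception was the circadian clock list, whose median of -0.25 with 5 RPKM added lay in the lowest 2.5% of random lists; the cause was not tested. Of 22 recalculated gene counts, 18 stayed within 1.5 times. The others were those with 5 RPKM added, 1392 higher and 830 lower, and those at 4-fold, 781 higher and 279 lower, where the stricter limit or the added constant removes genes by construction. Requiring a counting interval that excludes 1 left 2109 and 1546, so depth limited few of the 2-fold calls. With no added constant, members of the 24 lists past 2-fold numbered 183 higher and 60 lower, against 173 and 52. Scaling moved all log2 ratios by between -0.12 (centred on the reference genes) and 0.04 (the authors' scaling), and the share of 2-fold calls in the higher direction was 57.7% as reported and 48.7% when centred on the reference genes, which turned the majority. Centring and the authors' scaling shift every gene alike and so cannot change a list's percentile. Medians under these settings are among the 252 by construction. Of 801 recalculated values of named genes, 641 moved by no more than the mean distance, in log2 units, from the ratio to its counting limits. The other 160 moved by more, 79 of these with 5 RPKM added, and none changed sign. The 641 include 90 values with no filter and 81 with a mean of at least 5 RPKM, which a filter cannot move. The indolic glucosinolate median ranged from 1.497 to 2.05 over its settings, the aliphatic one from -0.14 to 0.03 and the photosynthesis one from -2.76 to -2.60. The abscisic acid and cold median, not called apart, ranged from -0.25 to 0.73, the highest with a mean of at least 5 RPKM. With 1 library per group no replicate could be left out. No paired analysis was possible because the replicates were pooled before sequencing.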

Other observations

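The tests of green tissue, clock phase (in all its groupings) and scaling, the starvation list without the filter and the grouping of gene families by symbol were chosen only after the values were seen; the tests of the starvation program and of overlapping genes were set before their results were seen. Gene families were formed from the letters of the reference symbols where at least 15 members were measured, which gave 46 families, 10 of them with a median in the highest 2.5% of matched random lists and 6 in the lowest. The highest median log2 ratio was that of the ERF genes, 1.36 over 20 genes, with 12 at least 2-fold higher and 0 lower. Of these ERF genes, 5 already belonged to a list set beforehand. Cysteine-rich receptor-like kinases (CRK), a class with roles in stress signalling and no member in the 24 lists, had a median log2 ratio of 1.03 over 30 genes, with 15 at least 2-fold higher and 0 lower. Among tau-class glutathione transferases (GSTU), 10 of 25 were higher and 1 lower, with a median of 0.77. Glycosyltransferases (UGT) had 16 of 43 higher and 4 lower, with a median of 0.61, and EXO-named genes, many of them for exocyst subunits in secretion, 7 of 18 higher with a median of 0.59. Calcium-dependent kinases (CPK) had 9 of 19 higher and a median of 0.79. The other families in the highest 2.5% were WRKY, given with the lists, NUDT with a median of 0.48, BGLU with 0.40 and NAC with 0.16.

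On the lower side, the auxin-inducible SAUR genes had a median log2 ratio of -1.06 over 15 genes, with 8 at least 2-fold lower and 2 higher. Genes named GRF, a symbol shared by growth-regulating factors and 14-3-3 proteins, had a median of -0.61 over 17 genes, and the UMAMIT transporters, which move amino acids, one of -0.49 over 31 genes with 6 lower and 0 higher. Genes named CYP, mostly for cytochromes P450 but a symbol that cyclophilins also carry, had a median of -0.34 over 132 genes, at percentile 0, though more of them were at least 2-fold higher (30) than lower (22). The other families in the lowest 2.5% were AGP, with a median of -0.37, and EMB, with -0.22. Families share members with homologous sequence, so reads can be divided among copies, and 1 library per group leaves these values without a replicate check.

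Photosynthesis genes formed the lowest list, and 3 technical readings were tested. A lower share of green tissue in the flg22 library would lower these genes by about the same factor. Their log2 ratios ranged over 4.03, with quartiles at -2.98 and -2.02, so it cannot be the whole cause. That reading would also place the root markers higher. As a set they were not higher, with 6 above 0, 8 below and a median of -0.28. Because they went both ways, they do not decide the question by themselves. Scaling to the library total is argued against by the reference genes, whose median log2 ratio was 0.12. For a different clock phase at harvest the result depended on the grouping: the median of the evening genes TOC1, LUX, ELF4, BOA and GI lay 1.24 above that of the morning genes CCA1, PRR7, PRR9, RVE8, LNK1 and LNK2, but 0.96 above it with the dawn gene RVE1 added, and 0.32 with PRR5, ELF3, FKF1 and GRP7 also counted as evening genes. The labels give no hour of harvest, so a clock difference and an effect of flg22 itself, on these genes or on the clock, both stay open.

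The 10 lowest ratios included that of SEN1, known to be induced in darkness. The hypothesis was raised that the control library carried a stronger carbon-starvation or dark program. A list of 19 further genes of that program was written before their values were looked at; its median log2 ratio over 18 measured genes was -1.46, at percentile 0 of matched random lists, with 11 genes at least 2-fold lower with flg22 on that scale (13 with no added constant) and 0 higher. The remaining gene, DIN2 (AT3G60140), lay under 1 RPKM and went against the hypothesis, with 10 reads in the control library and 88 with flg22, 7.65-fold higher (3.97 to 16.5); over all 19 genes the median was -1.40, at percentile 0. Among members outside the naming rule, picked after their values were seen, KMD4 (AT3G59940) was 10.5-fold lower (9.57 to 11.6), DRM1 (AT1G28330) by 8.63-fold (8.16 to 9.14) and MCCA (AT1G03090), of leucine breakdown, by 5.76-fold (5.26 to 6.31), while GDH2 (AT5G07440) had a log2 ratio of 0.97. The median fits the hypothesis, which may reflect a difference in light, medium or handling between the groups or an effect of flg22. With 1 pool per group these cannot be separated. Beside this, 30 of 31 photosynthesis genes were at least 2-fold lower with flg22, and so higher in the control library. A darker control alone would not account for that list, and darkness and carbon starvation were not tested apart.

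F3H was listed at 0 reads in both libraries beside other flavonoid genes with reads, and reads in overlapping gene models that were not counted are a candidate explanation. Among protein-coding genes with a curated symbol, 22 of 118 (18.6%) with at least 90% of their span under another annotated gene were at 0 in both libraries, against 563 of 7690 (7.32%) without overlap, a ratio of 2.55. With 50 to 90% of the span covered it was 5.26%, and with less it was 1.76%, both below the share without overlap. The values are consistent with the explanation only for part of the nearly covered genes, most of which had reads, and such genes may also be expressed less. The explanation does not cover AOP3, also listed at 0 in both libraries, which has 0% of its span under another gene; the antisense gene over F3H was not analysed here, and no biological explanation of the genes at 0 was tested.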
